A study of Halobacterium salinarum with 202 samples.

How the data were processed

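The study followed transcript levels in Halobacterium salinarum NRC-1, a halophilic archaeon, through time courses of hydrogen peroxide (H2O2) and paraquat, a redox cycler that makes superoxide inside the cell. Total RNA of each culture sample was labelled with one of 2 dyes, Alexa 546 or Alexa 647, and hybridised to a spotted 2-colour array together with a common reference RNA of mid-log cells. Per the labels' protocols, RNA was prepared with a miniprep kit, tested for DNA by PCR and checked for integrity on a Bioanalyzer.

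The deposited array files hold, per the file headers, the mean and median intensity of each spot and of its local background for each dye, on the linear scale of the scanner and without background subtraction. Each dye has 2 sets of columns, ending in H and L; the meaning of these endings and the quantification software are not given in the sources used here, and the H columns were used. The authors' series matrix holds log10 ratios of sample over reference; its scale and direction were found by setting each column against the log10 ratio of that array's own spots. Across bright spots of an array (over 1000 above background in both channels), which are not independent replicates, the correlation ranged from 0.423 to 0.993 (mean 0.917) and the slope from 0.583 to 1.01 (mean 0.870). The column medians ranged from -0.184 to 0.210 (median 0 over arrays), so how the authors centred each column is unknown beyond their statement that the 75th percentiles of the channels were made equal. Between 0 and 55.0% (mean 14.9%) of the values of a column were exactly 0, and the rule behind these zeros is not given in the sources used here. The authors' matrix was therefore used as an alternative only.

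The samples fell into 7 series and 51 groups of one series and time. The 202 arrays were taken as pairs, each RNA sample being hybridised on 2 arrays with opposite dyes; arrays were joined by series, time, OD and run of array numbers, and by the run alone in the short series, for which the labels give no OD. The constant stress series had 2 cultures each, in a short course (-1 to 160 min) and a long course (0 to 240 min). The recovery series followed cells for up to 240 min after 2 h with the agent, a wash and resuspension in fresh complete medium, with 3 cultures for H2O2 (2 at 240 min) and 2 for paraquat. A further paraquat series at 0.25 mM had 1 culture and was described without a test. The dose of each remaining series, 25 mM H2O2 or 4 mM paraquat, comes from the design text, not from a label of each sample.

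From the mean spot intensities and the median local background, background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3 with the package data.table (version 1.17.8). Within each array the 2 channels were scaled to equal 75th percentiles, as the design text states. The log2 ratio of sample over reference was turned by the dye labels; the 4 spots of a feature were averaged, and then the 2 opposite-dye arrays of one RNA. No filter on dim features was used. The arrays carry 2688 features. A name was given for 133 of them (532 of the spots), and the symbols of all 133 were found in the RefSeq table of another strain of the species, 91-R6, while 0 of the old numeric gene identifiers were; none of its coordinates were used. The remaining 2555 features are unnamed here and appear as the identifier of their first spot. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

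The limma model had one coefficient per group and shared one estimate of the spread over all groups (50 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of single features are limma's. The comparisons were the mean of 40, 80 and 160 min minus -1 min in the short series, the mean of 30, 60, 120 and 240 min minus 0 min in the long series, the mean of 60 and 120 min minus 0 min in recovery, and the difference between agents in each. A log2 change is given ± its standard error. The spread covers culture, RNA and array together. The fit treats RNA samples of the same culture as independent. The times averaged in a comparison thus count as separate replicates, although they come from 2 or 3 cultures.

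The design text states that aliquots of a culture were collected over time, so RNA samples with the same culture number were taken as pairs; the numbers were inferred from runs of array numbers. Their deviations from the group means correlated at a mean of 0.235 over 198 pairs of times within a culture (142 over 0.1, lowest -0.428, highest 0.867), and limma's duplicateCorrelation estimated 0.274. This pairing was settled after the calls with a block had been seen. The fit fixed beforehand has no block, and values with the culture as a block stand beside results whose call it changed or whose count it moved by more than 1.5 times.

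These comparisons, the alternatives and the gene lists were fixed before the data were examined. Of 20 lists, 7 had at least 3 named members and were tested with limma's camera at a preset inter-gene correlation of 0.01: chaperones and proteolysis, DNA repair, phototrophy, the TCA cycle, nucleotide biosynthesis, cobalamin biosynthesis, and motility and taxis. A further 4 lists with 2 named members each (ROS scavenging, ribosomal proteins, the respiratory chain, arginine and DMSO metabolism) were described by member, and the other 9 lists were not analysed here because no named feature belonged to them. The 9 calls of these lists over all samples without a block were repeated with an estimated correlation, and none of them held. The same was done, after the calls were seen, for the 4 list calls given below that were gained with the culture as a block or without 1 culture. Genes named in the text were, in each comparison, the 6 largest rises and falls among features past the threshold with the same sign in every culture, up to 3 members of each list, and dpsA and msrA; after it was seen that most features carry no name, and before any change was computed, the first part was also applied to the genes with a name. Under alternatives, counts cover all features, while single calls were followed only for the genes so chosen.

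A feature was counted as above background on an array where more than 2 of its 4 spots had a mean intensity over 1.5 times the median local background, and as saturated where more than 2 had a median intensity of at least 65000. Where a gene was above background on no array of a group, or saturated on all of them, no fold is given. On the arrays, 19.2 to 99.8% of spots (median 76.3%) were above background in the sample channel and 27.6 to 96.5% (median 78.5%) in the reference channel, and the 75th percentile of the background-subtracted sample channel ranged from 196 to 4129 (median 1707). The number of cultures and arrays limits the precision. No slide or scan date column was found in the files, so neither could be tested as a batch. In the short series the arrays of the 2 agents fell in separate runs of array numbers, so run and agent cannot be told apart there. Each comparison subtracts the first time of its own series, which takes out only a constant shift between runs. Control spots could not be told from other unnamed spots and were not removed.

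The pipeline was tested on simulated data of normal noise, independent between features and RNA samples, with the measured spread of each feature and 200 of the 2688 features changed. Of the simulated log2 changes of 1, 96, 94, 94, 95, 97 and 92% were recovered in the H2O2 short, H2O2 long, paraquat short, paraquat long, H2O2 recovery and paraquat recovery comparisons; of those of 0.5, 58, 66, 59, 63, 73 and 53%. Features left unchanged made up 4.19 to 5.56% of the calls. Alternatives covered loess or median scaling, no background correction, the authors' matrix, filters on dim features, each dye alone, the samples of each series alone, the culture as a block, another pairing of dye swaps, a fold threshold and leaving out each culture. A filter to features of above-median intensity and a camera test among named genes only were added after the data were seen. The L columns were tried with the same background correction, gave unusable values and were dropped.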

Results

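Transcripts of H. salinarum NRC-1 were compared before, during and after oxidative stress, on 202 arrays, 2 for each RNA sample, against a common reference RNA. Cells under constant stress received 25 mM H2O2 or 4 mM paraquat and were followed in a short series (7 times, 2 cultures and 14 RNA samples per agent) and a long series (5 times, 2 cultures and 10 RNA samples per agent). Cells in recovery were washed after 2 h with the agent and followed over 9 times, with 26 RNA samples of 3 cultures after H2O2 and 18 of 2 cultures after paraquat. A single culture with 0.25 mM paraquat gave 9 RNA samples. The questions, from the design text, were how transcripts change under constant stress and how they change once the agent is gone. No untreated culture was followed over time, so changes under constant stress cannot be told apart from changes with time or growth. Over the long series the OD rose 1.33 and 1.35 times with paraquat and 1.14 and 1.19 times with H2O2. Of the 2688 features, 133 carried a gene name, so gene groups below are described only through these. Signal differed between arrays: with the sample in Alexa 546, culture 1 of the H2O2 short series had a median of 34.9% of spots above background and culture 1 of the paraquat long series 30.7%, against a median of 76.3% over all arrays.

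During the first hours in 4 mM paraquat, dpsA, which encodes a ferritin-like protein that stores iron and binds DNA, rose by a log2 change of 0.81 ± 0.20, adjusted p = 0.00145, and msrA, a methionine sulfoxide reductase that repairs oxidised protein, rose by 0.47 ± 0.10, adjusted p = 2.96e-04. Each rise was of like size in both cultures, with dpsA saturated on 1 of 12 arrays after (0.79 and 0.83 for dpsA, 0.47 and 0.46 for msrA). The transcript of carB, the large subunit of carbamoyl phosphate synthetase, fell (-1.59 ± 0.29, adjusted p = 2.67e-05), as did both named ribosomal protein genes, rpmC (-1.30 ± 0.21, adjusted p = 2.74e-06) and rpl12p (-1.01 ± 0.22, adjusted p = 2.48e-04). The folate gene folP fell too (-1.05 ± 0.24).

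Of the 7 lists tested, camera called 1 in this comparison, nucleotide biosynthesis, with 7 of 12 members lower, 0 higher and 5 past no threshold, and the same 7 lower when adjusted over the list alone. Its members purF, the first enzyme of purine synthesis (-1.16, above background on 9 of 12 arrays after treatment), purL (-0.99), the cytidylate kinase gene cmk (-0.72) and the pyrimidine gene pyrF (-0.69, 10 of 12) fell. The list was called down with a median of -0.46 (adjusted p = 0.00150; adjusted p = 0.137 with an estimated correlation). In the TCA cycle 3 of 5 members fell (3 over the list alone): sucD (-0.74) and sucC (-0.63), which together encode succinyl-CoA synthetase, and the malate dehydrogenase gene mdh (-0.31). Among 4 cobalamin genes, cobN (-0.80) and cbiT (-0.86) fell (2 over the list alone).

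In phototrophy 3 of 4 members rose (3 over the list alone): sop1, the sensory rhodopsin I gene (0.52), the halorhodopsin gene hop (0.34) and the regulator gene bat (0.51, above background on 3 of 4 arrays before and 8 of 12 after). In motility and taxis 3 of 11 rose, 0 fell and 8 were not called (3 rose over the list alone): htr7 (0.74), htr1, the transducer partner of sensory rhodopsin I (0.56), and htr18, which was not well above background on any array before treatment and on 10 of 12 after. The excision repair gene uvrB rose (0.55 ± 0.12), as 1 of 4 DNA repair genes (1 over the list alone). Chaperones and proteolysis split, with psmB, a proteasome subunit gene, higher (0.33), the co-chaperone gene dnaJ lower (-0.29) and 3 of 5 members not called (1 and 1 over the list alone). The arginine deiminase gene arcA rose (0.62; arcC 0.35, called only over the list alone). Neither respiratory gene was called, at -0.15 for nuoL and -0.17 for sdhC. Camera called none of the 6 lists other than nucleotide biosynthesis (adjusted p = 0.172 to 0.988). The chaperone list had a median of 0.11 with the test pointing down, and DNA repair a median of -0.06 with a mean of 0.07 and the test pointing up.

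Over all features, limma called 880 (407 higher, 473 lower; 1140 at unadjusted p under 0.05), all with the same sign in both cultures; 77 of them changed by at least 1 on the log2 scale. Of the 133 named genes, 57 were called (15 higher, 42 lower). The unnamed features with the largest changes were probe_4007 (2.27 ± 0.23) and probe_4729 (2.13 ± 0.26), each above background on 3 of 4 arrays before, and probe_1215 (-1.73 ± 0.22) and probe_1279 (-1.59 ± 0.24). With 1 culture left out, the other being assumed to vary like the remaining groups, the count was 359 without culture 1 and 381 without culture 2. With the sample in Alexa 546 alone 510 were called, and 1461 when only the samples of this series entered the fit. The calls of carB, rpmC, rpl12p, purL, cmk, pyrF, msrA and htr7 held with either culture out. That of dpsA did not (adjusted p = 0.0637 and 0.0770, range over all alternatives 2.67e-06 to 0.0770). Of the 25 called genes chosen for the text here, 17, among them purF, folP, sucC, sucD, mdh, cobN, cbiT, uvrB, arcA, hop, sop1, bat, htr1, htr18, psmB and dnaJ, lost the call without at least 1 culture (adjusted p between 0.0548 and 0.518). The call of bat was also lost under loess scaling and in the authors' matrix. With the culture as a block cbiG passed as well (adjusted p = 8.64e-04), and camera called the cobalamin list down (median -0.58, adjusted p = 0.0173; adjusted p = 0.180 with an estimated correlation).

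In the long paraquat series, with other cultures and their own 0 min samples, the same stress genes rose. The log2 change was 0.78 ± 0.20, adjusted p = 0.00209 for dpsA (1.10 and 0.47 in the 2 cultures) and 0.39 ± 0.10, adjusted p = 0.00251 for msrA, which was above background on 3 of 4 arrays before and 12 of 16 after. The ribosomal protein genes rpmC (-1.22 ± 0.20, adjusted p = 1.09e-05) and rpl12p (-1.19 ± 0.21, adjusted p = 2.76e-05) fell, and with them infB, a translation initiation factor gene (-0.97 ± 0.17), secY, the channel of the protein secretion machinery (-0.92 ± 0.17), cmk (-0.86 ± 0.13) and the histidine biosynthesis gene hisF (-0.86 ± 0.12). After treatment infB and hisF were above background on 11 of 16 arrays, cmk on 13, rpmC on 14 and rpl12p on 15, and dpsA was saturated on 3.

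Nucleotide biosynthesis had 4 members lower, 1 higher and 7 not called of 12 (4 and 1 over the list alone), with pyrF at -0.58 (above background on 3 of 4 arrays before and 8 of 16 after) and purE, which rose, at 0.36 (12 of 16 after). The list's median was -0.31 and camera called it down (adjusted p = 0.0340; adjusted p = 0.446 with an estimated correlation). In the TCA cycle sucD (-0.68), sucC (-0.58) and the isocitrate dehydrogenase gene icd (-0.19, lost under loess scaling) fell, 3 of 5 by either adjustment. In phototrophy sop1 (0.53), bat (0.69) and hop (0.33, lost with channels scaled to equal medians) rose, 3 of 4 by either adjustment. In motility and taxis 4 of 11 rose by either adjustment, among them htr18 (0.89 ± 0.20, above background on 2 of 4 arrays before and 11 of 16 after), htr1 (0.60) and htr6 (0.49). Before treatment sop1, bat, hop, htr1, htr6 and mutL were above background on 3 of 4 arrays each, and after it on 13, 10, 12, 16, 12 and 9 of 16. Among 4 DNA repair genes mutL (0.39) was called by either adjustment, a call lost under loess and median scaling and in the matrix. No chaperone, cobalamin or arginine gene was called by either adjustment (dnaJ -0.14, psmA 0.22, cbiT -0.53, arcC -0.39). The respiratory genes nuoL (-0.27) and sdhC (-0.21) were called only over the list alone. The gene of the surface glycoprotein, csg, was saturated on every array. Lists other than nucleotide biosynthesis were not called by camera (adjusted p = 0.132 to 0.990). For chaperones the median (0.13) and the test, which pointed down, differed in sign.

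Limma called 945 features here (552 higher, 393 lower; 1288 at unadjusted p under 0.05), 935 of them with the same sign in both cultures, and 275 higher against 325 lower in the authors' matrix. With only the samples of this series in the fit, and so their own spread, limma called 0 (483 at unadjusted p under 0.05). The count was 309 with the sample in Alexa 546 alone and 495 in Alexa 647 alone. Of the named genes 49 were called (17 higher, 32 lower). The unnamed extremes were probe_4729 (1.43 ± 0.25, above background on 3 of 4 arrays before), probe_4007 (1.43 ± 0.22), probe_3125 (-1.35 ± 0.21) and probe_1085 (-1.35 ± 0.24). Culture 1, whose Alexa 546 arrays were dim, changed more than culture 2: without it 130 features were called, and the calls of dpsA (0.47, adjusted p = 0.307, range over all alternatives 5.93e-06 to 0.307), msrA (0.27, 0.193, range 6.88e-05 to 0.291) and the nucleotide list (adjusted p = 0.315, range 0.00571 to 0.446) were lost, as were those of sop1, bat, hop, htr1, htr6, htr18, mutL, purE, sucC, sucD and icd (adjusted p up to 0.914 over the 14 of 21 called genes chosen for the text that lost a call without at least 1 culture). The calls of rpmC, rpl12p, infB, secY, cmk, hisF and pyrF held without either culture. Without culture 2 the TCA cycle list was called down (median -0.15, adjusted p = 0.0158; adjusted p = 0.233 with an estimated correlation), and psmA, uvrB, nuoL, cbiT and arcA passed (adjusted p = 0.0426, 0.0190, 0.0344, 0.0296 and 0.0113). Genes called only with the culture as a block were, with adjusted p, uvrB (0.00713), nuoL (0.00344), sdhC (0.0491), cbiT (3.21e-04), cbiG (0.00281) and arcC (0.0326).

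The short and long paraquat series share no RNA. Across the 2688 features, which are not independent replicates, their log2 changes correlated at r = 0.845, and 96.8% of the features called in the short series had the same sign in the long one. Features higher in both numbered 256 (83.6 for independent lists), lower in both 312 (69.2 for independent lists), and 3 were called in opposite directions. Without culture 1 of the long series r was 0.649.

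**Figure D1:**
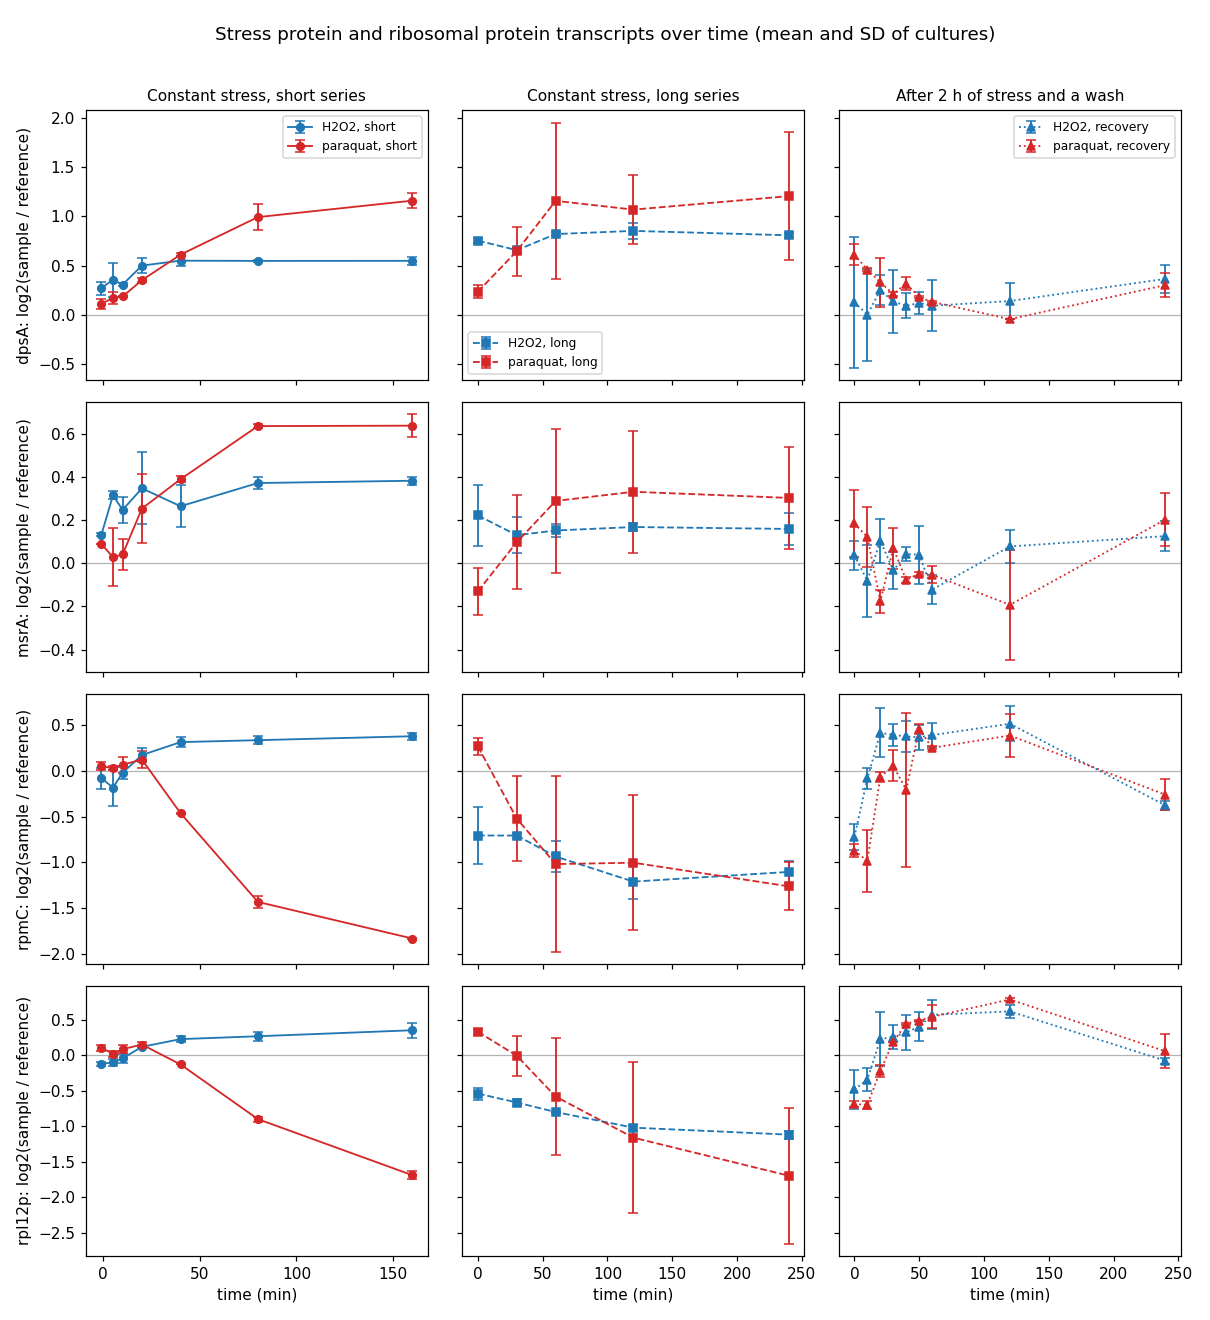
Levels of dpsA, msrA, rpmC and rpl12p as log2 of sample over reference (vertical axes) against time in minutes (horizontal axes), for H2O2 in blue and paraquat in red; points are means of the cultures (2 per point, 3 for most of H2O2 recovery) and bars their SD. Under paraquat dpsA rose (0.81 in the short series) while rpmC (-1.30) and rpl12p (-1.01) fell, and both ribosomal genes rose after the wash.

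With 25 mM H2O2 in the short series, the response differed from that to paraquat in part of its leading genes. The median change of all features was 0.18, and -0.01 under loess scaling, so changes in this comparison are given relative to the median of all features. Limma's test, its standard errors and all calls are of the change without this subtraction, which stands first where a p is given. The strongest named fall was in glyA, serine hydroxymethyltransferase, which links serine, glycine and folate metabolism (-1.00 ± 0.14, adjusted p = 2.63e-06, and -1.18 relative to the median; -0.98 and -1.01 in the 2 cultures, unsubtracted). The genes sucC (-0.81 ± 0.18, adjusted p = 0.00126, and -0.99 relative to the median) and sdhC, a subunit of succinate dehydrogenase (-0.57 ± 0.10, adjusted p = 8.03e-05, and -0.75 relative to the median), also fell, as did serS (-0.86), the phosphoserine phosphatase gene serB (-0.71) and panB of pantothenate synthesis (-0.68). The last 3 were above background on 11, 9 and 8 of 12 arrays after, and panB on 3 of 4 before. Called higher were pheA, prephenate dehydratase of phenylalanine synthesis (0.75 ± 0.17, adjusted p = 0.00120, and 0.58 relative to the median), trpC of tryptophan synthesis (0.45, above background on 2 of 4 arrays before and 10 of 12 after), the carbamate kinase gene arcC (0.44, above background on 3 of 4 arrays before) and radB, a RecA-family recombination gene (0.38 ± 0.08, adjusted p = 0.00151, and 0.20 relative to the median, above background on 2 of 4 arrays before and 11 of 12 after). In the short paraquat series glyA (-0.50), sucC (-0.63) and serS (-0.50) were called lower too and trpC higher (0.36), without subtraction. For these genes and arcC the difference between agents was not called. It was called for sdhC, serB, panB, pheA and radB.

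The stress genes that rose under paraquat did not pass here without a block. The change was 0.28 ± 0.20, adjusted p = 0.299, and 0.10 relative to the median for dpsA. It was 0.21 ± 0.10, adjusted p = 0.130, and 0.03 relative to the median for msrA, above background on 2 of 4 arrays before and 11 of 12 after, which passed with the culture as a block (adjusted p = 0.0384). The ribosomal protein genes stood at 0.24 (rpmC) and 0.22 (rpl12p) relative to the median, and all 4 were uncalled by either adjustment. Nucleotide biosynthesis had 1 of 12 members called higher, ndk (0.38, and 0.21 relative to the median), by either adjustment. In the TCA cycle sucC fell and icd was called higher at 0.26, which is 0.08 relative to the median (1 and 1 of 5 by either adjustment). One chaperone-list gene of 5, psmB (-0.44), fell (2 higher and 2 lower over the list alone). In motility and taxis cheY, the flagellar response regulator gene, fell (-0.52), and the call of htr18 rests on arrays where it was not well above background (1 and 1 of 11 by either adjustment). DNA repair had 1 of 4 called higher, radB (2 over the list alone). No member of phototrophy (bat 0.16, above background on 1 of 4 arrays before and 2 of 12 after) or cobalamin (cbiG 0.12) was called by either adjustment. Of the respiratory pair sdhC fell and nuoL stood at 0.10, called higher only over the list alone; arcA stood at -0.13. The genes mamA and htr18 were not well above background on any array, and hutU on none before and 3 of 12 after. Camera called no list (adjusted p = 0.308 to 0.698, against 0.628 to 0.757 with an estimated correlation). Relative to the median of all features, the list medians were -0.07 for nucleotide biosynthesis, -0.18 for motility and -0.19 for cobalamin, with the test pointing down for each. For phototrophy the median (-0.01) and the mean (0.0067) differed in sign, with the test pointing up.

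Limma called 504 features (354 higher, 150 lower; 993 at unadjusted p under 0.05), each with the same sign in both cultures. The balance turned with the scaling, to 170 higher and 169 lower with channels scaled to equal medians and to 102 higher and 203 lower under loess; the authors' matrix gave 239 and arrays with the sample in Alexa 647 alone 79. Only 8 changed by at least 1 on the log2 scale. Of the named genes 26 were called (16 higher, 10 lower); the calls of icd, ndk and htr18 were lost under loess, and those of serS, serB, panB and arcC in the matrix. Among unnamed features above background on all arrays, probe_5053 rose by 1.11 ± 0.29 and probe_1471 (-1.06 ± 0.19) and probe_3259 (-0.96 ± 0.15) fell, without subtraction of the median. The count was 45 without culture 1, the culture with dim Alexa 546 arrays, and 219 without culture 2. The calls of glyA and sdhC held without either culture. The genes sucC, pheA and trpC lost theirs without culture 1 (adjusted p = 0.156, 0.122 and 0.409; ranges over all alternatives 3.93e-08 to 0.156, 1.04e-09 to 0.122 and 2.64e-04 to 0.409), radB without either, and 15 of the 17 called genes chosen for the text without at least 1 culture (adjusted p between 0.0593 and 0.604). The culture as a block raised the count to 927 (663 higher, 264 lower), and with it, besides msrA, passed psmA (0.0125), pan1 (0.00953), uvrB (0.00654), rpmC (0.0302), rpl12p (0.0414), nuoL (0.00510), sucD (0.0452), cmk (0.00919) and cbiG (0.00913), with adjusted p in parentheses.

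In the long H2O2 series no feature passed without a block, and 9 did with the culture as a block (6 higher, 3 lower). Against its 0 min samples dpsA stood at 0.03 ± 0.20 (95% interval -0.36 to 0.43), msrA at -0.07 ± 0.10 (-0.27 to 0.13), rpl12p at -0.36 ± 0.21 (-0.79 to 0.06) and rpmC at -0.28 ± 0.20 (-0.69 to 0.12). The purine gene purD stood at -0.39 ± 0.14 and cheY at 0.32 ± 0.11 (adjusted p = 0.786 and 0.727); cheY passed with the culture as a block (adjusted p = 0.0481). Without a block no member of any list was called, over all features or over the list alone. Camera called nucleotide biosynthesis down (median -0.10, adjusted p = 5.77e-04; adjusted p = 0.0932 with an estimated correlation; adjusted p = 0.129 without culture 2, range over all alternatives 4.88e-06 to 0.129) and motility and taxis up (median 0.08, adjusted p = 0.0158; adjusted p = 0.487 with an estimated correlation; adjusted p = 0.0740 and 0.129 without culture 1 or 2, range 9.50e-04 to 0.487). The remaining lists had adjusted p = 0.267 to 0.910, with medians of -0.09 for the TCA cycle, 0.06 for chaperones, -0.03 for DNA repair, 0.07 for phototrophy and 0.01 for cobalamin, whose test pointed down. Without culture 1 the TCA cycle list was called down (-0.13, adjusted p = 0.0475; adjusted p = 0.336 with an estimated correlation). Over the respiratory pair the values were -0.16 (nuoL) and 0.04 (sdhC), and for arcA and arcC 0.10 and 0.02.

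For this comparison limma called 0 of 2688 features, with 119 at unadjusted p under 0.05 and a smallest adjusted p of 0.129; 2 were called under loess, 1 in the matrix, 9 with the culture as a block and 16 with only the samples of this series in the fit. Across features, which are not independent replicates, its changes correlated with those of the short H2O2 series at r = -0.160, and at r = 0.0944 without culture 1 of the long series. Among features of above-median intensity r was -0.362. Of the 504 features called in the short H2O2 series, 30.4% had the same sign in the long one, without subtraction of the median.

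**Figure D2:**
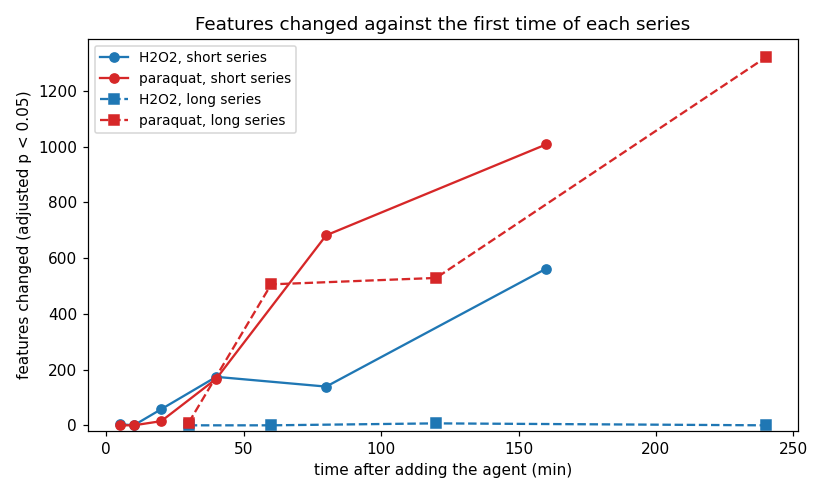
Number of features past the threshold (vertical axis) at each time against the first time of the same series (horizontal axis, minutes), for both agents and both constant stress series of 2 cultures. The paraquat short series went from 0 features at 10 min to 1008 at 160 min (504 without culture 1, 477 without culture 2), while the H2O2 long series had 0 at 240 min (13 with the culture as a block).

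Over time in the short paraquat series the counts were 0 at 5 and 10 min, 15 at 20 min, 167 at 40 min, 682 at 80 min and 1008 at 160 min. In the long series they were 10 at 30 min, 506 at 60 min, 529 at 120 min and 1321 at 240 min. For H2O2 the short series gave 4, 0, 58, 174, 139 and 562 at 5, 10, 20, 40, 80 and 160 min, and the long series 0, 0, 7 and 0 at 30, 60, 120 and 240 min. Each count rests on 2 cultures: at 160 min the paraquat short series gave 504 without culture 1 and 477 without culture 2, at 80 min 129 and 193 and at 40 min 3 and 4. The H2O2 short series at 160 min gave 42 and 85, and the paraquat long series 601 at 240 min, 70 at 120 min and 5 at 60 min without its culture 1. Without culture 2 of the paraquat long series 145 were called at 30 min, 1216 at 60 min and 1051 at 120 min, and without culture 1, 1 at 30 min. The H2O2 short series gave 7 and 19 at 80 min, 2 without culture 1 at 40 min, 2 and 8 at 20 min and 0 and 1 at 5 min; the H2O2 long series at 120 min and the paraquat short series at 20 min gave 0 without either culture. The culture as a block gave 1, 73 and 470 at 10, 20 and 40 min of the paraquat short series and 126, 860 and 886 at 30, 60 and 120 min of the long one. For H2O2 it gave 15, 34, 209, 520, 373 and 988 at the 6 times of the short series and 1, 11 and 13 at 60, 120 and 240 min of the long one.

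Among the genes with a name, the ribosomal protein genes had the largest log2 differences between H2O2 and paraquat in the short series. Here too the median of all features moved, from 0.12 to -0.02 under loess, and differences are given relative to that median, while the test, its standard errors and the calls are again of the difference without subtraction. After H2O2 both rpmC (1.72 ± 0.29, adjusted p = 2.15e-05, and 1.60 relative to the median) and rpl12p (1.42 ± 0.31, adjusted p = 6.26e-04, and 1.30 relative to the median) were higher than after paraquat, as were pheA (1.29 ± 0.23, adjusted p = 4.69e-05, and 1.17 relative to the median), secY (0.89), folP (0.83) and the enolase gene eno of glycolysis (0.80). Under paraquat itself pheA, looked up there after this difference was seen, fell (-0.54). Lower after H2O2 than after paraquat were htr1 (-0.88), htr7 (-0.72), panB (-0.79), srp19 of the signal recognition particle (-0.78), serB (-0.74), psmB (-0.59 ± 0.13, adjusted p = 8.13e-04, and -0.71 relative to the median), cheY (-0.63) and sdhC (-0.52). Before H2O2, htr7, srp19, radB, purM, pyrF and msrA were above background on 2 of 4 arrays.

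For nucleotide biosynthesis, 5 of 12 members were higher after H2O2 and 0 lower (8 and 0 over the list alone), among them purM (0.70), pyrF (0.50) and ndk (0.45). The list's median was 0.46 relative to that of all features (camera adjusted p = 0.0189; adjusted p = 0.441 with an estimated correlation; adjusted p = 0.0539 without culture 2 of the paraquat series, range over all alternatives 0.00849 to 0.441). Motility and taxis had 4 of 11 lower by either adjustment, with a median of -0.23 relative to all features (adjusted p = 0.0189; adjusted p = 0.515 with an estimated correlation; adjusted p = 0.0710 without culture 1 of the paraquat series, range 0.00520 to 0.515). One of 5 chaperone-list genes was higher, dnaJ (0.34), and 1 lower, psmB (1 and 2 over the list alone). DNA repair had 1 of 4 higher by either adjustment, radB (0.36). No member of phototrophy (sop1 -0.44), the TCA cycle (icd 0.09) or cobalamin (cbiG 0.55) was called by either adjustment, and these lists had adjusted p = 0.460, 0.604 and 0.460. For dpsA (-0.53 ± 0.29, adjusted p = 0.204, and -0.65 relative to the median) and msrA (-0.26 ± 0.14, adjusted p = 0.222, and -0.38 relative to the median) the difference between agents did not pass without a block, and that of dpsA did with it (adjusted p = 0.0322). Without a block arcA (-0.69) and nuoL (0.31) did not pass over all features.

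This difference was called for 491 features (316 higher, 175 lower; 844 at unadjusted p under 0.05), 171 higher and 243 lower with channels scaled to equal medians and 214 higher and 294 lower under loess. Without background correction the count was 290 and in the authors' matrix 280. With the sample in Alexa 546 or 647 alone it was 278 or 305, and 869 with only the samples of these series in the fit. It was 239 without culture 1 of the H2O2 series and 212 and 285 without culture 1 or 2 of the paraquat series. Calls of rpmC, rpl12p, pheA, secY, eno and radB held without any 1 culture, while 13 of the 19 called genes chosen for the text, htr1, htr7, cheY, sdhC, folP, purM, panB, serB, srp19, psmB, pyrF, ndk and dnaJ, lost theirs without at least 1 (adjusted p between 0.0509 and 0.291). The calls of secY, folP and ndk were lost under loess, those of folP, purM and dnaJ under median scaling, and those of purM, pyrF, cheY, sdhC and serB in the matrix. With the culture as a block 843 were called (549 higher, 294 lower), and besides dpsA these passed, with adjusted p: psmA (0.0212), uvrA (0.0468), nuoL (0.00164), icd (0.0473), cbiG (5.37e-05), cbiT (2.63e-04), cobN (3.10e-04) and arcA (0.0351). Camera then called the cobalamin list higher (adjusted p = 0.0457; adjusted p = 0.241 with an estimated correlation).

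**Figure D3:**
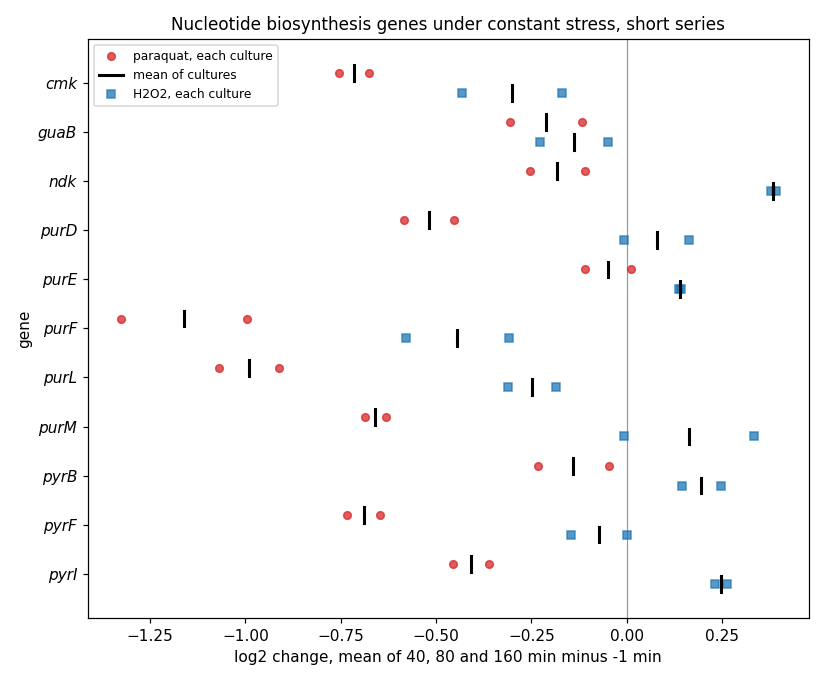
Log2 change of 11 nucleotide biosynthesis genes (vertical axis; purB, not well above background, is left out) as the mean of 40, 80 and 160 min minus -1 min (horizontal axis), with a point per culture for paraquat (red circles) and H2O2 (blue squares) and a black bar at their mean; the median of all features is not subtracted (0.18 for H2O2). The paraquat points of purF (mean -1.16), purL (-0.99) and cmk (-0.72) lie furthest to the left.

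In the long series the agents differed at fewer genes. After H2O2 the changes were higher than after paraquat for cmk (0.75 ± 0.18, adjusted p = 0.0134), gdhA2, a glutamate dehydrogenase gene (0.68 ± 0.15, adjusted p = 0.00740), rpmC (0.94 ± 0.29, adjusted p = 0.0466), hisF (0.65) and the thiamine gene thiL (0.52), and lower for purE (-0.56) and moaC of molybdenum cofactor synthesis (-0.44). For msrA (-0.46 ± 0.14, adjusted p = 0.0501) and dpsA (-0.75 ± 0.28, adjusted p = 0.0999) the difference did not pass over all features; both passed over their 2-gene list alone and with the culture as a block (adjusted p = 0.00250 and 0.00386). Nucleotide biosynthesis had 1 higher and 1 lower of 12 (2 and 1 over the list alone), its median (-0.0069) and mean (0.07) differing in sign, as did those of the chaperones (0.07 and -0.01). No other list had a called member except the ribosomal pair (2 over the list alone; rpl12p 0.83), and camera called no list (adjusted p = 0.373 to 0.732). Members uncalled included sucC (0.56), sop1 (-0.46), htr18 (-0.80, above background on 2 of 4 arrays before paraquat), uvrB (-0.34), pan1 (-0.33, on 8 of 16 after it), cbiT (0.65), sdhC (0.25) and arcC (0.41). Limma called 105 features (71 higher, 34 lower; 597 at unadjusted p under 0.05). The count was 52 with channels scaled to equal medians, 65 in the matrix, 1 and 21 with the sample in Alexa 546 or 647 alone, 1 with only the samples of these series in the fit, 0 (318 at unadjusted p under 0.05) and 46 without culture 1 or 2 of the H2O2 series, and 11 and 679 without culture 1 or 2 of the paraquat series. The calls of all 7 named genes were lost without at least 1 culture (adjusted p between 0.0736 and 0.665). Under median scaling those of rpmC (also in the matrix), hisF, purE and moaC were lost, as was that of thiL under loess. Without culture 2 of the paraquat series dpsA (-1.07, adjusted p = 0.00470), msrA (-0.57, 0.00248), sucD (1.15, 1.04e-07), rpl12p, sucC, pyrF, uvrB, sop1, bat and htr18 passed. The culture as a block gave 459 features (266 higher, 193 lower), and besides msrA and dpsA passed, with adjusted p, uvrB (0.0306), sop1 (0.0275), rpl12p (0.00480), sucC (0.00318), sucD (0.0155), pyrF (0.0143), cbiT (0.00513) and htr18 (0.0107).

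After H2O2 was washed out, both named ribosomal protein genes rose in all 3 cultures. The log2 change from 0 min to 60 and 120 min was 1.18 ± 0.18, adjusted p = 1.16e-06 for rpmC and 1.08 ± 0.19, adjusted p = 1.37e-05 for rpl12p. The gene phoU, which encodes a regulator of phosphate uptake, rose as much (1.18 ± 0.19, adjusted p = 1.95e-06; 1.28, 0.89 and 1.35 in the 3 cultures; above background on 5 of 6 arrays before). Rises in all 3 cultures were also measured for arcC (0.96 ± 0.15), secY (0.90 ± 0.15) and speB, annotated as an agmatinase of polyamine synthesis (0.82 ± 0.11). The proteasome-activating nucleotidase gene pan1 fell (-1.06 ± 0.18, adjusted p = 8.80e-06, above background on 7 of 12 arrays after), with the glutamate dehydrogenase gene gdhA1 (-0.76 ± 0.19) and hisG, the first enzyme of histidine synthesis (-0.58 ± 0.11, above background on 10 of 12 arrays after).

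Nucleotide biosynthesis divided within the list, with 3 members higher and 5 lower of 12 by either adjustment. Its kinase gene cmk (0.71) and pyrF (0.48) rose, and purF (-0.76), purM (-0.71) and purD (-0.55) of the purine pathway fell, each above background on 11 of 12 arrays after. Chaperones also divided: dnaJ (0.46) and dnaK (0.53) rose while pan1 fell (2 and 1 of 5 by either adjustment). In motility and taxis htr2, the transducer of sensory rhodopsin II, rose (0.39) and htr6 fell (-0.53), 1 and 1 of 11 by either adjustment. Of the respiratory pair sdhC was called higher (0.24, lost under loess and median scaling and in the matrix), and nuoL (0.21) passed over the list alone. Both arginine genes were called higher, arcA at 0.48 with culture values of 1.29, 0.0042 and 0.15. No TCA cycle (icd 0.13), DNA repair (radB -0.16), phototrophy (sop2 0.16) or cobalamin (cbiQ 0.12) gene was called by either adjustment. The stress genes dpsA (-0.01 ± 0.18) and msrA (-0.06 ± 0.09, above background on 11 of 12 arrays after) did not pass. Camera called no list (adjusted p = 0.977 for each); the signs of median, mean and test differed for chaperones (median 0.04, mean -0.03, test up), DNA repair (median 0.08, test down) and the TCA cycle (median 0.13, test down).

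Limma called 771 features (509 higher, 262 lower; 988 at unadjusted p under 0.05), 745 of them with the same sign in all 3 cultures. The split was 300 higher and 336 lower with channels scaled to equal medians and 345 and 361 under loess, and the count 440 with the sample in Alexa 546 alone. Of the named genes 48 were called (35 higher, 13 lower). Unnamed extremes were probe_3153 (1.40 ± 0.12, above background on 5 of 6 arrays before), probe_5021 (-2.04 ± 0.27, above background on 7 of 12 arrays after) and probe_1605 (-2.02 ± 0.37). With 1 of the 3 cultures left out, 7 of the 21 called genes chosen for the text lost their call in at least 1 case: arcA (0.08, adjusted p = 0.810), dnaK (0.33, 0.0757) and gdhA1 (-0.59, 0.0513) without culture 1, purF without culture 1 (0.379) or 3 (0.108), sdhC without culture 1 (0.161) or 3 (0.261), and htr6 (0.0882) and hutU (0.218) without culture 3. With the culture as a block these passed, with adjusted p: uvrB (0.0243), sop2 (0.0393), nuoL (0.00943), icd (0.0427), mdh (0.0437) and htr1 (0.00215). Without culture 1 htr1 passed (-0.57, 0.00271), and without culture 2 nuoL (0.0308). Ranges over all alternatives were 0.00223 to 0.810 for arcA, 9.73e-06 to 0.0757 for dnaK, 2.41e-07 to 0.0513 for gdhA1, 6.23e-04 to 0.379 for purF, 0.0124 to 0.878 for sdhC, 2.24e-04 to 0.0882 for htr6 and 3.65e-04 to 0.728 for hutU.

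Washed out of paraquat, cells again raised the ribosomal protein genes, rpl12p by 1.35 ± 0.23, adjusted p = 7.12e-06 and rpmC by 1.19 ± 0.22, adjusted p = 2.44e-05, in both cultures. The genes cmk (1.07 ± 0.14), speB (0.98 ± 0.13), eno (0.95 ± 0.12) and orc8 of the replication origin recognition family (0.91 ± 0.13, above background on 2 of 4 arrays before) rose as well. Here phoU fell (-1.45 ± 0.23, adjusted p = 1.30e-06; -1.11 and -1.78 in the 2 cultures), the opposite of its change after H2O2. The gene pan1 fell again (-1.21 ± 0.22, adjusted p = 2.16e-05, above background on 4 of 8 arrays after), as did hisG (-0.80), moaC (-0.72), htr6 (-0.87) and htr1 (-0.79).

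Both stress genes were lower after the wash, dpsA at -0.57 ± 0.22, adjusted p = 0.0411 and msrA at -0.31 ± 0.11, adjusted p = 0.0260. The dpsA call was lost with channels scaled to equal medians and in the matrix, and without culture 1 or 2 (adjusted p = 0.441 and 0.217, range over all alternatives 1.99e-04 to 0.441). The msrA call was lost in the matrix and without culture 1 (-0.09, adjusted p = 0.878, range 0.00267 to 0.878). Nucleotide biosynthesis had 3 higher and 1 lower of 12 by either adjustment, with pyrF (0.61) and ndk (0.48) among the rises; its median (-0.02) and mean (0.07) differed in sign. Of the chaperone list dnaK (0.43) and dnaJ (0.37) rose and pan1 fell, 2 and 1 of 5 by either adjustment. In phototrophy sop1 (-0.57) and hop (-0.36, lost under loess and median scaling) fell, and in DNA repair mutL (-0.42, above background on 2 of 4 arrays before and 6 of 8 after) and radB (-0.24), both lost under median scaling and in the matrix, 2 of 4 in each by either adjustment. Motility and taxis had 1 higher, htr2 (0.31), and 2 lower of 11 by either adjustment. The respiratory genes nuoL (0.41) and sdhC (0.34) rose, and 1 of 5 TCA cycle genes, icd (0.33), by either adjustment; these 3 calls and those of dnaK and ndk were lost under loess. At 0 min htr6, msrA, pyrF and hop were above background on 3 of 4 arrays. No cobalamin (cbiQ 0.26) or arginine (arcC 0.23) gene was called by either adjustment. Camera called no list (adjusted p = 0.392 to 0.946).

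Limma called 774 features after paraquat (459 higher, 315 lower; 982 at unadjusted p under 0.05), 773 of them with the same sign in both cultures; 89 changed by at least 1. Of the named genes 53 were called (35 higher, 18 lower). Unnamed extremes were probe_1547 (1.98 ± 0.28), probe_3141 (1.84 ± 0.25), probe_1605 (-2.33 ± 0.45) and probe_5021 (-2.25 ± 0.33, above background on 6 of 8 arrays after). The count was 262 without culture 1 and 439 without culture 2, and 12 of the 26 called genes chosen for the text lost their call without at least 1 culture (adjusted p between 0.0586 and 0.878), among them htr2, dnaK, hop, mutL, radB, nuoL, sdhC, sop1, ndk and pyrF. The count against 0 min was 11 at 10 min, 319 at 20 min, 334 at 30 min, 589 at 40 min and 607 at 50 and 60 min, and stood at 634 at 120 min and 240 at 240 min. Without culture 1 it was 0, 1, 23, 184, 175, 103, 197 and 10 at these 8 times, and without culture 2 it was 1, 32, 51, 227, 169, 276, 278 and 55. The culture as a block gave 120, 738, 618 and 489 at 10, 20, 30 and 240 min, and over 60 and 120 min, with adjusted p, citZ (0.0200), sucC (0.0391) and cbiQ (0.00478) passed as well.

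**Figure D4:**
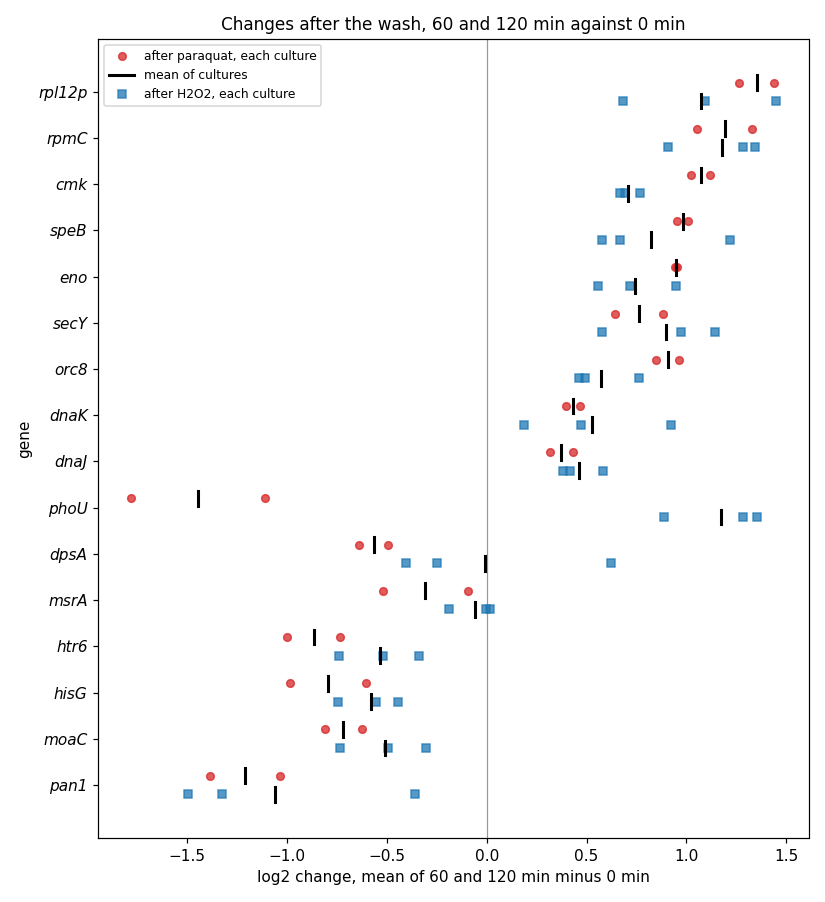
Log2 change from 0 min to the mean of 60 and 120 min after the wash (horizontal axis) for 16 named genes (vertical axis), with a point per culture after paraquat (red circles, 2 cultures) and after H2O2 (blue squares, 3 cultures) and a black bar at each mean. Points of both agents lie on the same side for rpl12p, rpmC, cmk and pan1, while phoU lies at -1.45 after paraquat and 1.18 after H2O2.

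The 2 recoveries share no RNA. Across features, which are not independent replicates, their changes correlated at r = 0.793; 350 features were higher in both (86.9 for independent lists), 189 lower in both (30.7) and 8 opposite (104). The test of H2O2 minus paraquat in recovery called 1 named gene, phoU, at 2.62 ± 0.29, adjusted p = 2.33e-09, and 2.58 relative to the median of all features. That median was 0.04 and moved to -0.10 with channels scaled to equal medians, so single differences and list medians below are relative to it where no p or standard error stands first, and calls are of the difference without subtraction. For dpsA (0.56 ± 0.28, adjusted p = 0.628, and 0.52 relative to the median) and msrA (0.25 ± 0.14, adjusted p = 0.738, and 0.21 relative to the median) the difference did not pass, nor for rpl12p (-0.32) and rpmC (-0.05). Without a block no list had a called member over all features or over the list alone, except arcA and arcC over theirs alone (0.55 and 0.69). Camera called the TCA cycle lower after H2O2 than after paraquat (median -0.14, adjusted p = 0.0189; adjusted p = 0.265 with an estimated correlation; led by citZ, -0.36), nucleotide biosynthesis lower (median -0.18, adjusted p = 0.0189; adjusted p = 0.265 with an estimated correlation; cmk -0.40) and motility and taxis higher (median 0.19, adjusted p = 0.0189; adjusted p = 0.360 with an estimated correlation; htr1 0.42). These list calls were lost without 1 culture each: the TCA cycle without culture 2 of H2O2 (adjusted p = 0.0754) or culture 1 of paraquat (0.307; range over all alternatives 0.00552 to 0.997), nucleotide biosynthesis without culture 1 of paraquat (0.0963; range 0.00107 to 0.392) and motility without culture 2 of paraquat (0.253; range 0.00154 to 0.533). The remaining lists had adjusted p = 0.237 to 0.622. Limma called 25 features (22 higher, 3 lower; 210 at unadjusted p under 0.05), 16 and 8 with channels scaled to equal medians and 23 and 7 under loess. The 3 lower ones, named because the count is small, were probe_1547, probe_1221 and probe_3031. The count was 14 without culture 1 of paraquat, 15 without culture 2 and 14 with the sample in Alexa 546 alone. With the culture as a block it was 87 (46 higher, 41 lower), and citZ (0.0342) and arcC (0.0464) passed, with adjusted p in parentheses.

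Recovery set against constant stress ran in opposite directions for paraquat. Across features the recovery change correlated with the stress change at r = -0.598 (short series) and -0.654 (long series), and 401 and 410 features were called in opposite directions, against 128 and 132 for independent lists. Both rpmC and rpl12p fell in the stress series and rose in recovery, while dpsA and msrA rose under stress and were lower after the wash. The gene phoU did not reverse: it was called lower in the short series (-0.79) and again in recovery (-1.45), and was not called in the long series (-0.39). For H2O2 the same correlations were -0.0660 and -0.260. Features are not independent replicates in any of these.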

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

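The tests of sample number, of dim features, of the weak culture, of wash and medium and of splits within cultures were chosen only after the result was seen. What brought these results here is a difference between the agents that passed limma's test of the difference itself; groups of at most 3 cultures were too small to look for single samples far from the rest. In the short series 491 features differed. Named genes higher after H2O2, as log2 differences without subtraction of the median of all features, were rpmC 1.72, rpl12p 1.42, pheA 1.29, secY 1.01, folP 0.95, eno 0.92, purM 0.82, pyrF 0.62, ndk 0.57, radB 0.48, dnaJ 0.46; those higher after paraquat were htr1 -0.76, panB -0.66, srp19 -0.66, serB -0.62, htr7 -0.60, psmB -0.59, cheY -0.51, sdhC -0.40. The list medians, unsubtracted too, were 0.58 for nucleotide biosynthesis and -0.11 for motility and taxis, calls lost with an estimated correlation (adjusted p = 0.441 and 0.515). In the long series 105 features differed, with rpmC 0.94, cmk 0.75, gdhA2 0.68, hisF 0.65, thiL 0.52, purE -0.56, moaC -0.44. In recovery 25 differed, with phoU 2.62 and list medians, likewise unsubtracted, of -0.10 for the TCA cycle, -0.14 for nucleotide biosynthesis and 0.23 for motility and taxis. These 3 list calls were lost with an estimated correlation (adjusted p = 0.265, 0.265 and 0.360), and the TCA cycle test turned with Alexa 647 alone.

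In the long H2O2 series limma called 0 features, with 119 at unadjusted p under 0.05, and 9 with the culture as a block. For log2 changes of 1, too few RNA samples were argued against by the simulated data with 200 features changed, where 94% were recovered. These data hold no shared culture effect. With fewer features changed the adjusted threshold is stricter, so for that case the simulated percentages can be too high and too few samples stay open. For smaller changes too few samples stay open, since 66% of those of 0.5 were recovered and smaller ones were not simulated. In the short H2O2 series only 8 of the 504 called features changed by at least 1. A swap of the 0 min label with another time of the series was argued against as well, since no other time set against the rest called more than 6 features. A stressed state already present at 0 min stays open: across features of above-median intensity, this RNA minus the -1 min RNA of the short H2O2 series correlated with the long paraquat change at r = 0.367, with dpsA at 0.48, rpmC at -0.63 and rpl12p at -0.42. Set against the -1 min RNA of the short paraquat series it correlated at r = 0.558. The 0 min RNA of the long paraquat series, minus the same -1 min RNA of the short H2O2 series, correlated with the short paraquat change at r = -0.230, with dpsA at -0.04, rpmC at 0.35 and rpl12p at 0.45. The -1 and 0 min RNA come from different experiments. A difference between experiments in growth or handling is thus part of each of these values. A weaker response of these cultures was not tested. Across features the long H2O2 change correlated with the long paraquat change, which shares no RNA with it, at r = 0.387. Above the median intensity r was 0.472. Of the 945 features called under paraquat, 73.2% had the same sign under H2O2. In the short series r between agents was 0.317, and 0.131 above the median intensity. Changes over time without an agent would enter these correlations too, as no untreated culture was followed.

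In the short H2O2 series rises outnumbered falls, 354 to 150, which could reflect technical rather than biological differences. Among features of above-median intensity 48.3% of calls were rises, and without culture 1, the culture with dim Alexa 546 arrays, 28.9% were, so both explanations stay open. The balance also turned with the scaling, to 170 higher and 169 lower with channels scaled to equal medians and to 102 higher and 203 lower under loess. The excess of rises thus depended on the processing. No biological explanation of this imbalance was tested.

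The 2 recoveries were alike, at r = 0.793 across features, which may come from a return from stress or from the wash and fresh medium. For a return, the state at 0 min, taken against the -1 min RNA of the short series of the same agent, and the recovery of other cultures correlated at a mean of r = -0.281 after H2O2 and -0.729 after paraquat, against a bound of -0.3 for both set beforehand, which leaves the H2O2 side undecided. The wash and the medium cannot be told apart from recovery itself, because no washed untreated culture was in the design. Against its own 0 min RNA, H2O2 recovery gave 616 features at 120 min and 85 at 240 min. The RNA of 0 and 120 min came from 3 cultures and that of 240 min from 2, without culture 1. These counts thus differ in the cultures used as well as in time. Against the 0 min RNA of the long series of the same agent, limma called 265 at 0 min (3 cultures) and 109 at 240 min (2 cultures) after H2O2. After paraquat it called 377 and 33. The RNA compared here comes from different experiments, so these counts do not separate the causes. Chance as the origin of the H2O2 recovery count was looked at through splits of its 9 RNA samples. Like the real one, 27 splits put 1 sample of each of the 3 cultures in the smaller group. Of these only the real split gave as many features (776 in that fit, and 120 in the highest other split). The other 26 put a sample of a later time in the smaller group for at least 1 culture. Any trend over time shared by the cultures would thus favour the real split as well. Of all 84 splits into 6 and 3, again only the real one gave as many (highest other 359). This argues against a count that any split would give, but with 3 cultures it cannot exclude chance.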

How the results depend on the processing

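The alternatives with only the features of above-median intensity and with camera among the named genes only, and the estimated correlation for list calls gained under an alternative, were chosen after seeing the data; the tests of all other alternatives here were set before the data were examined. Of the values of the genes chosen for the text under alternatives, 3911 of 4580 kept their side of the threshold, 484 lost the call and 184 gained it. One turned, icd in H2O2 recovery under loess (-0.13). Of the list values 903 of 957 kept their side, 41 lost the call and 12 gained it. One turned by the direction of its test, the TCA cycle in H2O2 minus PQ recovery with Alexa 647 alone (median -0.0576). Direction was compared only for values called in the main fit or under the alternative. Values uncalled in both count as kept whatever their sign. Counts of called features that moved by more than 1.5 times, and other values that moved, were these. Loess within array: H2O2 short 305, H2O2 long 2. Channels scaled to equal medians: H2O2-PQ long 52. No background correction: H2O2-PQ short 290. The authors' series matrix values: H2O2 short 239, H2O2 long 1, PQ long 600, H2O2-PQ short 280, H2O2-PQ long 65, short/long r, H2O2 -0.483. Only features of above-median intensity: H2O2 short 288, PQ long 606, short/long r, H2O2 -0.362. Of the 54 list values run in that setting 7 lost their call, against 9 list calls over all features. Only arrays with the sample in Alexa 546: PQ short 510, PQ long 309, H2O2 recovery 440, H2O2-PQ short 278, H2O2-PQ long 1, H2O2-PQ recovery 14, short/long r, PQ 0.722. Only arrays with the sample in Alexa 647: H2O2 short 79, PQ long 495, H2O2-PQ short 305, H2O2-PQ long 21, list calls 5. Only the samples of the series compared: H2O2 long 16, PQ short 1461, PQ long 0, H2O2-PQ short 869, H2O2-PQ long 1. Adjusted p and absolute log2 fold change of at least 1: H2O2 short 8, PQ short 77, PQ long 37, H2O2 recovery 36, PQ recovery 89, H2O2-PQ short 102, H2O2-PQ long 11. Without H2O2_short replicate 1: H2O2 short 45, H2O2-PQ short 239. Without H2O2_short replicate 2: H2O2 short 219. Without H2O2_long replicate 1: H2O2-PQ long 0, short/long r, H2O2 0.0944. Without H2O2_long replicate 2: H2O2-PQ long 46. Without PQ_short replicate 1: PQ short 359, H2O2-PQ short 212. Without PQ_short replicate 2: PQ short 381, H2O2-PQ short 285. Without PQ_long replicate 1: PQ long 130, H2O2-PQ long 11, short/long r, PQ 0.649. Without PQ_long replicate 2: H2O2-PQ long 679. Without PQ_recovery replicate 1: PQ recovery 262, H2O2-PQ recovery 14. Without PQ_recovery replicate 2: PQ recovery 439, H2O2-PQ recovery 15. Estimated inter-gene correlation: list calls 0. The other ends of the ranges with 1 culture left out were PQ long 1283, H2O2-PQ short 335, H2O2-PQ recovery 27, short/long r, H2O2 -0.262 and short/long r, PQ 0.852. Fewer features, arrays or cultures enter where the setting leaves some out, and a culture left alone was assumed to vary like the other groups; otherwise the cause was not tested. Where limma called 0 features, 483 (PQ long, samples of the series alone) and 318 (H2O2-PQ long, without H2O2_long replicate 1) had an unadjusted p under 0.05. Crossing the dye pairs of the short series, adding the 0 min RNA of OD 0.659 and the planned filter on dim features moved no count by that much. Culture numbers were taken as pairs, which was settled after the calls with a block were seen. Replicate block: culture: H2O2 short 927, H2O2 long 9, H2O2-PQ short 843, H2O2-PQ long 459, H2O2-PQ recovery 87. Random culture block: H2O2 short 896, H2O2 long 5, H2O2-PQ short 812, H2O2-PQ long 399, H2O2-PQ recovery 58. With the culture as a replicate block 48 of the 302 values of genes chosen for the text and 2 of the 63 of lists gained a call, each given with its result, and no other of these calls changed. Opposite dyes correlated, across features, at r = 0.766, 0.562, 0.933, 0.917, 0.868 and 0.883 above the median intensity and at 0.044, 0.131, 0.618, 0.582, 0.531 and -0.199 below it, in the order H2O2 short, H2O2 long, PQ short, PQ long, H2O2 recovery and PQ recovery. Values of dim features thus agreed less between the dyes. Noise and an effect of the dye were not told apart, and the cause was not tested.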

Other observations

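The list tests in this part were chosen only after the result was seen, while the description of the 0.25 mM culture was set before the data were examined. They cover 3 lists (aminoacyl-tRNA synthetases, histidine biosynthesis, histidine degradation) in 6 comparisons, 18 tests adjusted together. Of 12 aminoacyl-tRNA synthetase genes, whose products charge tRNAs for translation, 5 were lower in each paraquat series and 6 higher after each wash. The named genes as a whole leaned the same way: of 133, 42 and 32 were lower in the short and long paraquat series. After each wash 35 of them were higher. Camera set these added lists against all 2688 features, and a test among the named genes only was not run for them. In the short paraquat series lysS (-0.89), proS (-0.45) and ileS (-0.41) were among 5 of 12 lower, with 0 higher; camera called the list down (median -0.25, adjusted p = 0.00450; adjusted p = 0.0412 with an estimated correlation). In the long series 5 were lower and 0 higher (median -0.16, adjusted p = 0.0223; adjusted p = 0.0969 with an estimated correlation; lost in the authors' matrix, 0.0503). After the wash 6 of 12 were higher and 0 lower with either agent, lysS at 0.42 after H2O2 and 0.79 after paraquat. The list medians were 0.20 (adjusted p = 0.0242; adjusted p = 0.0969 with an estimated correlation) and 0.27 (adjusted p = 0.00450; adjusted p = 0.0412 with an estimated correlation). With Alexa 647 alone both recovery calls were lost (0.0884 each), and the H2O2 one with equal medians (0.0716). Under H2O2 itself the list was not called (adjusted p = 0.259 and 0.333).

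Histidine biosynthesis did not move as a group: hisF, a cyclase subunit, fell under paraquat (-0.77 and -0.86) and rose after the wash (0.44 after H2O2, 0.76 after paraquat), while hisG (-0.58 and -0.80) and hisA (-0.54 and -0.61) fell after it. The smallest adjusted p of the list over the 6 comparisons was 0.270. For histidine degradation the adjusted p ranged from 0.146 to 0.420.

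One hypothesis is that genes of the translation apparatus beyond the ribosomal pair could follow the same course under paraquat. The list median of -0.25 for the synthetases, with both paraquat series called, is what this needs. However, the long-series call was lost with an estimated correlation (adjusted p = 0.0969) and in the authors' matrix (0.0503), and the list was found and tested on the same arrays. The OD of the 2 cultures rose 1.33 and 1.35 times over the long paraquat series and 1.14 and 1.19 times over the long H2O2 series, in which the list was not called. No untreated culture was followed, so growth without an agent is not known here.

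The culture with 0.25 mM paraquat was described without a test. Across features of above-median intensity, which are not independent replicates, its change from -1 min correlated with that of the 4 mM short series at the same time at r = 0.260 at 20 min, 0.390 at 40 min, 0.599 at 80 min and 0.588 at 160 min, where the slope was 0.261. It was 0.00667 at 5 min and 0.0363 at 10 min. Over all features r was -0.0185, 0.170, 0.426 and 0.280 at 20, 40, 80 and 160 min. At 160 min dpsA stood at 0.47, msrA at 0.01, rpl12p at -0.61, rpmC at -0.47 and carB at -0.50; at 320 min dpsA stood at 0.71, msrA at 0.19, rpl12p at -0.69, rpmC at -0.39 and carB at -0.50. In the authors' matrix r at 160 min was 0.406 and rpl12p stood at 0.20 at 160 min and 0.09 at 320 min, where msrA stood at -0.06. The other gene values named here kept their sign in the matrix. The OD of this culture was lower at 320 min than at -1 min.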
